A study of Homo sapiens with 4 samples.

How the data were processed

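JOK1 cells carrying a RhoH vector or an empty vector were compared on 4 two-colour Agilent arrays, with 2 arrays in each dye orientation. Per the file headers, the authors scanned the arrays at 10 micron and read them with Agilent Feature Extraction 9.1.3.1. The deposited scanner files hold, per spot and channel, the mean intensity, the median intensity of the local background, a processed intensity and quality marks. Per the file headers the processed intensity was detrended over the array surface, dye-normalised within the array, and replaced by a surrogate where low. The deposited log ratio is the log10 of Cy5 over Cy3 processed intensity, not turned by dye orientation. The deposited series table equals that log ratio in every spot (largest difference 0), so it is not a separate measurement. In 54416 spots the deposited log10 ratio differed by more than 0.001 from the ratio of the processed intensities. All of these had a log ratio of 0, 51553 had surrogates in both channels, and 76 of the 65248 spots of tested genes were among them.

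Each array holds 43931 spots, of which 2256 are controls. The other 41675 read 41000 different probes. Probe names were brought to current symbols by RefSeq accession (23146), symbol (2436) or older symbol (1114), and 14304 kept the name in the files. The genome build of the probes is not stated, so no positions are given. A current annotation (GRCh38) was used only for names and for the order of genes. Background was corrected by normexp with an offset of 50 on mean foreground and median background, and log2 ratios were normalised by loess within each array (span 0.3) in limma 3.58.1 (R 4.3.3). Control spots had no weight in the loess and were then left out, and spots of 1 probe were averaged. Probes were kept if well above background on at least 3 of the 4 arrays in the RhoH-vector or the empty-vector RNA (21429), and 239 with an outlier mark were left out. The brightest of the 21190 remaining probes stood for each of 15835 genes, of which 10549 have a current symbol. No spot was saturated.

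Ratios were fitted with limma with a RhoH term turned by dye orientation and a dye term. That leaves 2 residual degrees of freedom, to which the variance prior of limma adds 5.19. Tests were two-sided, and p-values were adjusted over all tested genes by Benjamini and Hochberg. Genes passed at an adjusted p under 0.05. A total of 27 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. The estimated correlations come from the 2 residual degrees of freedom, and that version of camera also takes its own degrees of freedom from them, which raises its p-values. Counts adjusted over the list alone are given beside those over all genes. The named genes are RHOH, the 12 largest rises and 12 largest falls among genes with a current symbol, an adjusted p under 0.05 and the same direction on all 4 arrays, up to 4 members of each list with the smallest adjusted p, and 9 markers of hairy cell leukemia named whatever their result. The rule was written before the data were examined. The results of 3 of the lists and of 1 gene among the largest rises are not reported here.

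The gene order, the runs of neighbouring genes and the comparison of arrays 1 and 2 with arrays 3 and 4 were chosen after values had been seen. For the runs, medians over windows of 25 genes were compared with limits of -0.15 and 0.14, taken from 1000 shuffles of the gene order. Each run was widened to the full windows around the genes whose running median passed a limit, and touching runs of the same direction were joined. A run therefore also holds genes whose own running median did not pass. The window and limits were set after a first look at the runs. The difference between the array sets was tested in limma as a term beside the RhoH and dye terms. With 3 terms on 4 arrays that fit leaves 1 residual degree of freedom, so its p-values lean on the variance prior.

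The fit was tested on simulated data with the spread of these arrays. Noise was drawn separately for each gene and array, and 200 of 15835 genes were changed in each round. It recovered 37.3% of genes changed by 0.3 on the log2 scale, 78.8% of those changed by 0.5 and 94.5% of those changed by 1, and 2.37% of its calls were unchanged genes. With nothing changed it called 0 genes. Of 100 unchanged lists 2% had a camera p under 0.05, and of 25 lists shifted by 0.2 the share was 100%. These lists were random and the simulated genes independent, while genes on the arrays are correlated, so these rates need not hold for the real data. The run search found the planted run in 20 of 20 rounds and a run in 1 of 20 shuffled orders.

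Alternatives changed the background correction, the normalisation, the filter, the dye term, the variance prior, the array weights, the probe rule, the source of the values, the pairing of arrays and the threshold, and left out each array in turn. Alternatives added after the data were seen were a random block for arrays 1 with 2 and 3 with 4, scan day as the unit, and the fit without the genes in runs. Slide or scan position as a block was planned on the condition of more than 1 day with more than 1 array. Of 3 scan days, 1 held 2 arrays, so it was not run as planned. Signal over background and the number of arrays limit the precision.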

Results

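JOK1, an established cell line of hairy cell leukemia (a B cell malignancy), was compared in 2 states: cells carrying a vector for RhoH and cells carrying the empty vector. RhoH is a protein of blood cells that binds GTP but does not hydrolyse it. The RNA of both states was hybridised together on each of 4 two-colour arrays, so every array is a direct comparison. The RhoH-vector RNA was in Cy5 on arrays 1 and 4 and in Cy3 on arrays 2 and 3. Of 41675 non-control spots per array, between 49.0% and 50.8% in Cy3 and between 54.0% and 54.6% in Cy5 were well above background on arrays 2, 3 and 4. On array 1 these shares were 74.1% and 84.6%. A total of 15835 genes were tested. All fold changes below are log2 ratios of the RhoH vector over the empty vector, given with the limma standard error (SE, n = 4 arrays). The number of arrays limits their precision. The labels do not say whether the arrays came from separate cultures, so the p-values measure only the spread between arrays, which may be technical.

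The first question was whether the RHOH transcript itself differed. The array has 1 RHOH probe, printed as 10 spots, and it was brighter than 89.2% of the tested genes' probes over both RNAs. Its log2 ratio was 0.11 ± 0.041 (95% interval 0.02 to 0.21, adjusted p = 0.096, limma), which did not pass the threshold. It was above 0 on 3 of 4 arrays, with values of 0.17, 0.09, -0.01 and 0.19. With median centring in place of loess the value was -0.01 (adjusted p = 0.96), and with arrays 1 and 3 and arrays 2 and 4 averaged as pairs the adjusted p was 0.048, which were the highest and the lowest adjusted p over the alternatives run. The median of all tested genes was -0.089 with median centring and -0.0013 with loess, so RHOH stayed above the median gene. The position of this probe in the transcript is not given in the sources used here. A probe outside the part carried by the vector reads only the cell's own transcript and so does not check the vector. The direction of every ratio therefore rests on the dyes given in the labels. After turning for the dyes, the log2 ratios of all 6 pairs of arrays correlated positively across genes, from 0.39 to 0.77 (genes are not independent replicates). The highest values were those of pairs with the same dye orientation, arrays 2 and 3 (0.77) and arrays 1 and 4 (0.67), which share the dye bias of probes. Pairs of opposite orientation ran from 0.39 to 0.56.

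Which genes differed between RhoH-vector and empty-vector cells? CD38, an ectoenzyme of activated B cells and plasma cells, fell 4.11-fold (-2.04 ± 0.19, adjusted p = 0.00057). IL15, a cytokine for T and NK cells, fell (-2.04 ± 0.19), but its probe was well above background on 2 of 4 arrays in the RhoH-vector RNA, so background limits the size read. BANK1, a B cell scaffold protein, fell 3.29-fold (-1.72 ± 0.041). JCHAIN, the joining chain of polymeric immunoglobulin, fell 2.96-fold (-1.57 ± 0.043). The largest rises were ACTG1, cytoplasmic gamma-actin, at 3.91-fold (1.97 ± 0.20, adjusted p = 0.00082), and RAMP1, a partner of calcitonin-family receptors, at 3.63-fold (1.86 ± 0.25).

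Also among the 12 named genes with the largest falls were GPR158 (-1.89), PTPRR (-1.76), SYBU (-1.64), LSAMP (-1.47), FAM30A (-1.45), the Fc receptor-like gene FCRL2 (-1.45), MIR99AHG (-1.31) and MPEG1 (-1.27). In the RhoH-vector RNA the probes of GPR158, PTPRR, SYBU and FAM30A were well above background on 1 of 4 arrays and that of LSAMP on 2, against 4 in the empty-vector RNA, so background limits the sizes and ranks of these falls. Also among the 12 with the largest rises were SMAD1 (1.30), which transmits bone morphogenetic protein signals, the ligand BMP7 (1.17), LGALS2 (1.26), the tumour antigen PRAME (1.20), TERT (1.19), the catalytic subunit of telomerase, PLEKHA5 (1.09), MYBPH (1.09), PBX4 (0.98) and FBLN5 (0.97). Each of the genes named so far other than RHOH had the same direction on all 4 arrays, as the naming rule required. Other probes were tested for ACTG1 (1.89 and 1.79), SMAD1 (1.76), FCRL2 (-1.67), MIR99AHG (-0.86), MPEG1 (-0.59), PRAME (0.45), FBLN5 (0.28) and PLEKHA5 (0.18). All had the sign of the brighter probe, but those of PRAME, FBLN5 and PLEKHA5 read much smaller changes. The ACTG1 probes may share signal with transcripts of similar actin sequence.

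In all, 1761 genes were higher and 1875 lower with the RhoH vector (adjusted p under 0.05, limma), or 23.0% of the genes tested. Most changes were small: the median size among them was 0.24 on the log2 scale, or 1.18-fold. At least 2-fold changes were found for 13 higher and 38 lower genes, against 62 and 126 with the Agilent processed signals and 32 and 93 with a normexp offset of 0. Of the 3636 genes, 3266 had the same direction on all 4 arrays, as had 33.6% of all tested genes, where 4 random signs give 12.5%. Averaging arrays 1 with 2 and 3 with 4 as technical pairs left 1103 higher and 1221 lower genes, the Agilent processed signals gave 888 and 1020, a fit without the dye term 1041 and 1137, and leaving out array 2 or array 3 gave 934 and 1088 or 1118 and 1155. Median centring, which leaves the dye trend with intensity in place, gave 224 higher and 1166 lower genes, or 16.1% higher against 48.4% with loess. Averaging arrays 1 with 3 and 2 with 4 gave 2727 and 2817. Of 111 changed genes that the naming rule took, 80 passed the threshold under all alternatives that tested them.

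**Figure D1:**
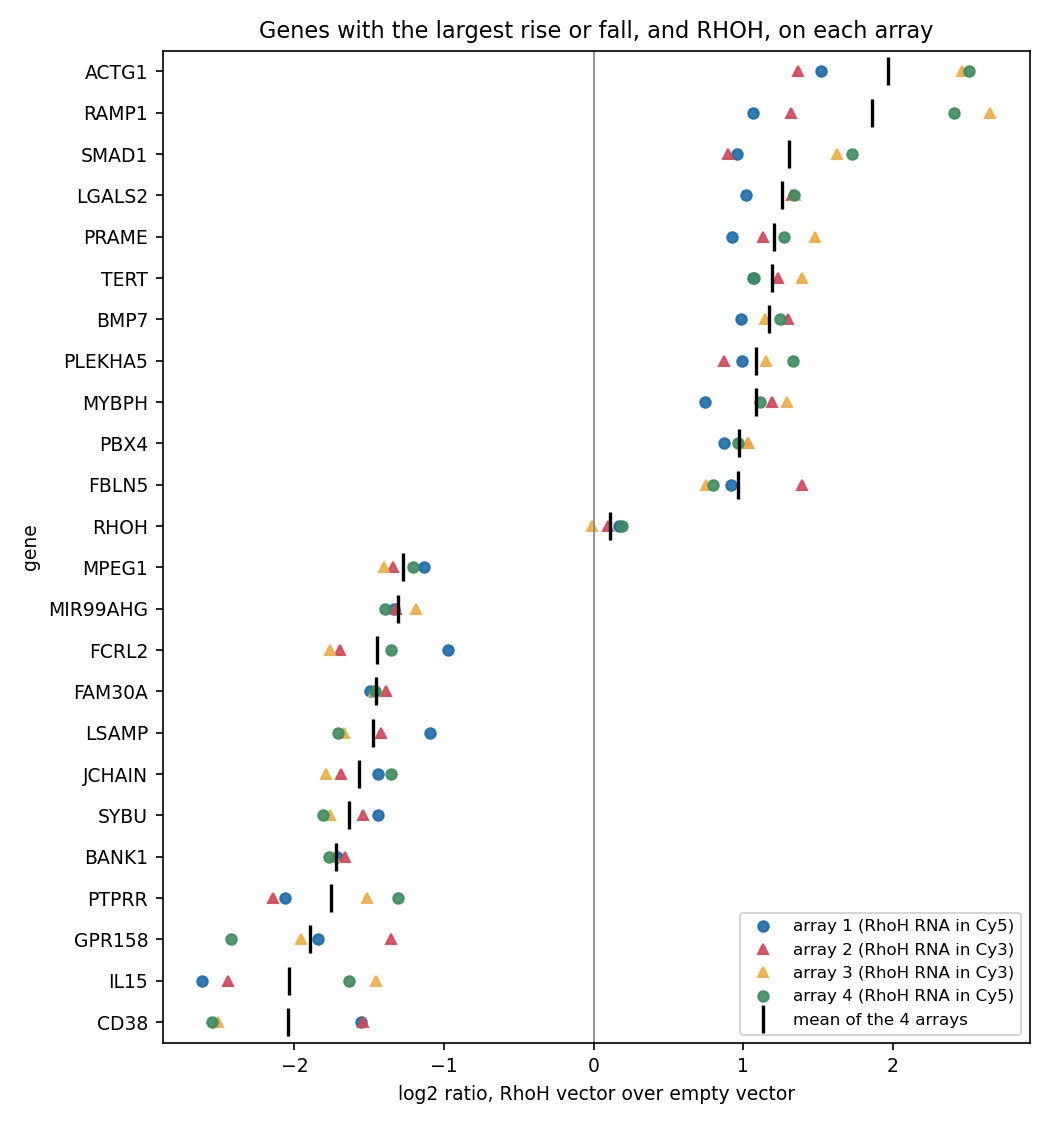
Log2 ratio of the RhoH vector over the empty vector (horizontal axis) for 11 of the 12 genes with the largest rise, RHOH and the 12 with the largest fall (vertical axis). Each point is 1 array, circles have the RhoH RNA in Cy5 and triangles in Cy3, and the bar is the mean of the 4 arrays: CD38 lies at -1.56 and -1.54 on arrays 1 and 2 and at -2.51 and -2.55 on arrays 3 and 4, and RHOH lies near 0.

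For several of these genes the size of the change differed between arrays 1 and 2 and arrays 3 and 4, which also differ in scan day. CD38 had a mean of -1.55 on arrays 1 and 2 and -2.53 on arrays 3 and 4, a difference of -0.98 (adjusted p = 0.00061 for the difference, limma). That test has 2 arrays per set and 1 residual degree of freedom, so its p-values lean on the variance prior. ACTG1 (1.44 and 2.49), RAMP1 (1.19 and 2.53), SMAD1 (0.93 and 1.68) and GPR158 (-1.60 and -2.19) were also larger in size on arrays 3 and 4. IL15 (-2.53 and -1.54) and PTPRR (-2.10 and -1.41) were larger in size on arrays 1 and 2. For GPR158, IL15 and PTPRR these sizes also depend on the background of each array, since the RhoH-vector RNA was well above it on at most 2 of 4. Across all genes 156 showed such a difference, 137 of them among genes well above background on all 4 arrays in both RNAs. Arrays 3 and 4 shared a scan day and held both dye orientations, so their mean is the value within that day. Over all tested genes the means of both sets correlated at 0.75 (across genes).

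Genes on the list of hairy cell leukemia markers moved in both directions. The list gives no direction for its members, so these counts do not show a shift toward or away from the disease. Of 16 tested members of this list, 5 rose, 6 fell and 5 did not pass, and the counts adjusted over the list alone were also 5 and 6. Beside CD38, ITGAX (CD11c) fell by 0.64 (SE 0.042), CD22 fell by 0.71 (SE 0.073) and CD27 (-0.49) fell. GAS7 (0.82) rose, as did ACP5, tartrate-resistant acid phosphatase (0.21 ± 0.041, adjusted p = 0.010), but ACP5 did not pass without array 3 (0.19) or with median centring (0.16). JUND passed the threshold (0.16 ± 0.041, adjusted p = 0.032), yet its ratio was 0.50 and 0.40 with the RhoH RNA in Cy5 and -0.13 and -0.14 with it in Cy3, so its direction followed the dye. JUND did not pass without array 1 (0.13), array 2 (0.16) or array 3 (0.16). ITGAE (CD103) was at 0.05 ± 0.049 (adjusted p = 0.48) and at -0.08 with median centring, under which all tested genes had a median of -0.089. CCND1, IL2RA (CD25) and ANXA1 were not tested, because none of their probes was well above background on more than 1 of 4 arrays in either RNA. The list as a whole was not shifted against other genes (camera adjusted p = 0.78), with a median of 0.0040, a mean of -0.16 and the camera direction lower, and with median centring it was called lower (adjusted p = 0.015).

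Of 24 tested genes of MHC class I and II presentation, 15 fell, 0 rose and 9 did not pass, and 18 fell when adjusted over the list alone. The members with the smallest adjusted p were HLA-DMB (-0.49 ± 0.041), the protease CTSS (-0.54 ± 0.050), HLA-DOB (-0.49 ± 0.053) and HLA-DQA1 (-0.42 ± 0.045). The list's median was -0.25 and it was called lower (camera adjusted p = 1.5e-08). With an estimated correlation the camera adjusted p was 0.34. That estimate, 0.0011, was under the preset 0.01, so a higher correlation among members did not raise the p-value. A second HLA-DOB probe was at 0.03 and a second HLA-DQA1 probe at -0.17, and probes of different HLA genes can share signal.

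Of 27 tested genes of cholesterol and fatty acid synthesis, 14 fell, 0 rose and 13 did not pass, and 19 fell when adjusted over the list alone. They included SQLE, squalene epoxidase (-0.72 ± 0.050), the sterol carrier STARD4 (-0.38 ± 0.039), FDPS (-0.35 ± 0.041) and the fatty acid elongase ELOVL6 (-0.30 ± 0.041). The list's median was -0.18 (camera adjusted p = 5.2e-07, adjusted p = 0.34 with an estimated correlation). Here too the estimate, -0.016, was under the preset 0.01.

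Of 38 tested genes of B cell receptor signalling, 19 fell, 2 rose and 17 did not pass, and 20 fell and 3 rose when adjusted over the list alone. Beside BANK1, the kinase LCK (-0.70 ± 0.049) and the adaptor PIK3AP1 (-0.50 ± 0.057) fell, while the ubiquitin ligase CBL (0.42 ± 0.049) rose. The list was called lower (camera adjusted p = 0.0015, adjusted p = 0.64 with an estimated correlation). Among integrins and adhesion molecules, 7 of 22 fell and 2 rose, with 8 and 2 when adjusted over the list alone. ITGB7 fell by 1.05 (SE 0.047), ITGAX and ICAM2 (-0.37) fell too, and ITGA6 (0.36) rose. That list was called lower (camera adjusted p = 0.021, adjusted p = 0.64 with an estimated correlation), but not without array 2 (adjusted p = 0.098) or array 3 (adjusted p = 0.065), in a range from 0.0040 to 0.64 over all alternatives.

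**Figure D2:**
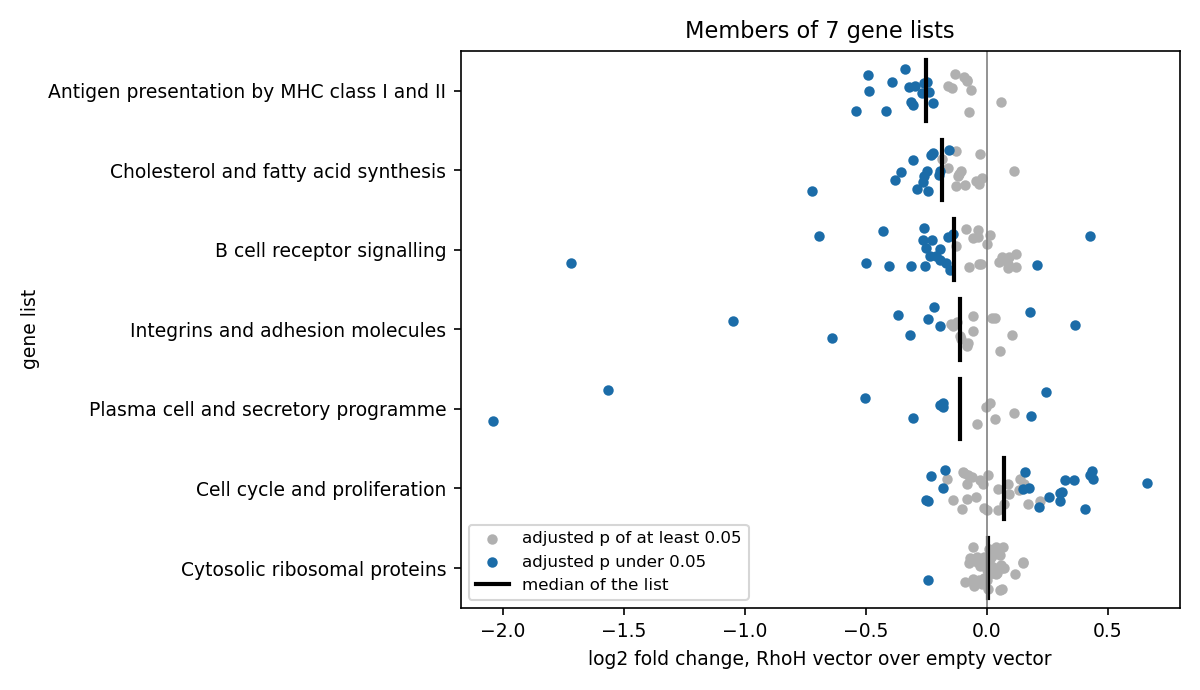
Log2 fold change of the RhoH vector over the empty vector (horizontal axis) for the tested members of 7 gene lists (vertical axis, points spread within a list for legibility). Blue points have an adjusted p under 0.05, grey points do not, and the bar is the median of the list, which is -0.25 for antigen presentation, -0.18 for cholesterol and fatty acid synthesis and 0.00 for ribosomal proteins.

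Other B lineage genes split. In the B cell identity list, 10 of 30 fell and 5 rose (12 and 5 adjusted over the list alone), and STAP1 (-0.70), the receptor TNFRSF17 (-0.50) and CD22 (-0.71) were among those that fell. In the plasma cell and secretory list, 7 of 14 fell and 2 rose (7 and 3 adjusted over the list alone), led by CD38, JCHAIN and TNFRSF17, with SEC11C (-0.31) also lower. Neither list was called (camera adjusted p = 0.16 and 0.077), but without array 1 both were called lower (adjusted p = 0.042 and 0.035), as they were with median centring (adjusted p = 0.030 and 1.5e-08). The plasma cell list was also called lower without array 2 and with no filter on dim probes (both adjusted p = 0.020).

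Several chemokine genes and 1 receptor gene rose. CCL3 (0.95 ± 0.085), CCL4 (0.82 ± 0.065), CCL5 (0.53) and the receptor CX3CR1 (0.76) were higher, among 4 of 17 members that rose and 3 that fell (also 4 and 3 adjusted over the list alone). The median of that list was -0.06 and its mean 0.11 (camera adjusted p = 0.78, direction higher). Of NF-kB targets, 9 of 30 fell and 2 rose (9 and 2 adjusted over the list alone). CD83 (-0.68) and CD86 (-0.38), both surface molecules of activated antigen-presenting cells, fell, but a second CD86 probe (-0.17) did not pass. In the JAK-STAT and cytokine list, 5 of 24 fell and 4 rose (7 and 4 adjusted over the list alone), with IL10 (-0.43) lower beside IL15 and IL7R (0.73) and IL3RA (0.37) higher. Of type I interferon response genes, 9 of 23 fell and 3 rose (10 and 4 adjusted over the list alone), with IFI35 (-0.38), RIGI (-0.34), IFI6 (-0.36) and PLSCR1 (-0.49) lower. None of these 3 lists was called (camera adjusted p = 0.077 for NF-kB, 0.65 for JAK-STAT and 0.082 for interferon). The NF-kB list was called lower without array 1 (adjusted p = 0.0040), without array 2 (adjusted p = 0.034) and with no filter on dim probes (adjusted p = 0.020), and the interferon list without array 2 (adjusted p = 0.034).

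Of 45 cell cycle genes, 15 rose and 5 fell (17 and 6 adjusted over the list alone). The mitotic genes UBE2C (0.66 ± 0.065), CCNB1 (0.43) and CDC20 (0.43) rose, as did TYMS (0.44). The list was not called (camera adjusted p = 0.077), but it was called higher without array 3 (adjusted p = 0.0092), without array 4 (adjusted p = 0.011) and with no filter on dim probes (adjusted p = 0.020). Of cyclins, CDK inhibitors and p53 targets, 5 of 26 rose and 5 fell (6 and 6 adjusted over the list alone), with the CDK inhibitors CDKN2C (-0.67) and CDKN1A (-0.46) and the death receptor FAS (-0.48) lower and RB1 (0.43) higher. Second probes of CDKN1A (-0.13) and RB1 (0.14) did not pass. This list's median was 0.04 and its mean -0.01 (camera adjusted p = 0.80, direction higher). Of apoptosis regulators, 8 of 34 fell and 6 rose (8 and 7 adjusted over the list alone), and the inflammatory caspases CASP4 (-1.11 ± 0.044) and CASP1 (-0.92 ± 0.052) fell, as did PMAIP1 (-0.63). That list was not called (camera adjusted p = 0.47), except as lower with median centring (adjusted p = 0.047).

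Of MAPK output and immediate early genes, 6 of 22 rose and 3 fell (8 and 3 adjusted over the list alone), with DUSP5 (0.38), KLF6 (0.30) and PHLDA1 (0.27) higher and EGR1 (-0.29) lower. In the unfolded protein response and stress list, 7 of 30 fell and 4 rose (10 and 5 adjusted over the list alone), with TRIB3 (0.62), HSPH1 (0.55) and ATF4 (0.31) higher and DDIT4 (-0.43) lower. A second TRIB3 probe read 0.29. Of replication-dependent histones, 8 of 26 fell and 0 rose (also 8 and 0 adjusted over the list alone), with H2BC12 (-0.73), H2BC14 (-0.31), H2AC18 (-0.43) and H1-2 (-0.37) lower. A second H2AC18 probe (-0.11) did not pass. Histone genes are near-identical copies, so their probes are uncertain. Of hypoxia and glycolysis genes, 4 of 25 fell and 2 rose (also 4 and 2 adjusted over the list alone), with ALDOC (-0.35), ANKRD37 (-0.24) and PGK1 (-0.26) lower and HK2 (0.32) higher. PGK1 did not pass without array 2 (-0.22), nor ANKRD37 without array 3 (-0.21). The camera adjusted p was 0.084 for MAPK output, 0.62 for stress, 0.082 for histones and 0.16 for hypoxia. Histones were called lower without array 1 (adjusted p = 0.0040), without array 2 (adjusted p = 0.00049) and with no filter on dim probes (adjusted p = 0.020).

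Of oxidative phosphorylation genes, 5 of 35 rose and 1 fell (4 and 1 adjusted over the list alone). SDHA (0.54), NDUFV2 (0.48) and COX8A (0.20) rose and ATP5F1A (-0.58) fell. COX8A did not pass without array 2 (0.19). Of 44 ribosomal protein genes, 1 fell, RPL4 (-0.24), and 0 rose (0 and 0 adjusted over the list alone). Of extracellular matrix genes, 2 of 12 fell and 1 rose (also 2 and 1 adjusted over the list alone), with ADAM8 (-0.48) lower. COL9A2 (-0.21) fell and COL9A3 (0.18) rose, but without array 2 neither passed (-0.14 and 0.17). RPL4 did not pass without array 1 (-0.17) or array 2 (-0.20), COL9A2 not without array 4 (-0.18), and COL9A3 not without array 1 (0.15) or array 3 (0.19). The camera adjusted p was 0.16 for oxidative phosphorylation and 0.80 for both other lists.

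Markers of other cell types did not move as groups. Of T and NK cell markers, 1 of 5 rose, UBASH3A (0.59 ± 0.14), at 0.96 on arrays 1 and 2 and 0.22 on arrays 3 and 4, with a probe well above background on 2 of 4 arrays in the empty-vector RNA, and it did not pass without array 2 (0.41). Of monocyte and granulocyte markers, 3 of 10 rose and 2 fell, with CSF1R (-0.95) and TLR4 (-0.65) lower and AIF1 (0.52) and FCN1 (0.45) higher. A second FCN1 probe (0.13) did not pass, and 2 other TLR4 probes read a smaller fall (both -0.21). Of 5 tested erythroid, fibroblast and epithelial markers, 0 passed. The counts adjusted over the list alone were the same for these 3 lists, and the camera adjusted p was 0.93, 0.86 and 0.77. The signs of median, mean and camera direction differed for T and NK markers (-0.03, 0.09, higher) and for monocyte markers (0.01, -0.03, higher). Across all 27 lists camera called 4 lower and 0 higher, and 9 lower without array 1 and 7 lower without array 2. With an estimated correlation it called 0 at an adjusted p under 0.05, and 2 lists, antigen presentation and cholesterol synthesis, had an unadjusted p under 0.05. fry, which asks whether a list's genes move one way on balance, called 5 lower, which were the 4 called by camera and the plasma cell list, and 1 higher, MAPK output (adjusted p = 0.030 for each of the last 2).

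Changes of genes that lie next to each other in the genome were correlated. Over 10534 tested genes placed in the gene order of GRCh38, the log2 fold change of a gene correlated with the mean of its 2 neighbours (r = 0.30 across genes). It was 0.18 with the 5% largest changes left out and 0.17 outside the runs described below. In 1000 shuffles of the gene order the highest correlation was 0.05 (permutation p = 0.001, the smallest they can give, one-sided). Genes whose running median over 25 genes left the range of shuffled orders made, with the rest of their windows, 10 runs of 775 genes. The runs therefore also hold genes whose own running median did not leave that range. The longest run covered 300 of the 304 tested genes of one chromosome, from C20orf96 to SOX18, with a median of 0.24, and 191 of its genes rose and 6 fell. On another chromosome the 46 genes from USP14 to RIOK3 had a median of 0.26 and the 105 genes from LDLRAD4 to PARD6G, which overlap them, a median of -0.26. The 48 genes from CCDC127 to IL7R had a median of 0.34 and the 57 genes from BAALC to ADGRB1 a median of -0.25. Named genes in such runs were TERT, SDHA and IL7R (CCDC127 to IL7R), BMP7, PREX1 (0.63), UBE2C, TRIB3 and COL9A3 (C20orf96 to SOX18), PLEKHA5 (C12orf60 to STK38L), SYBU and SQLE (BAALC to ADGRB1), TYMS and NDUFV2 (USP14 to RIOK3), SEC11C, PMAIP1 and ATP5F1A (LDLRAD4 to PARD6G), RB1 and HSPH1 (ZDHHC20 to THSD1), and HLA-DMB, HLA-DOB and HLA-DQA1 (TNXB to RGL2). With the run genes left out, 1365 genes were higher and 1654 lower, and the same number of lists, 4, was called lower.

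**Figure D3:**
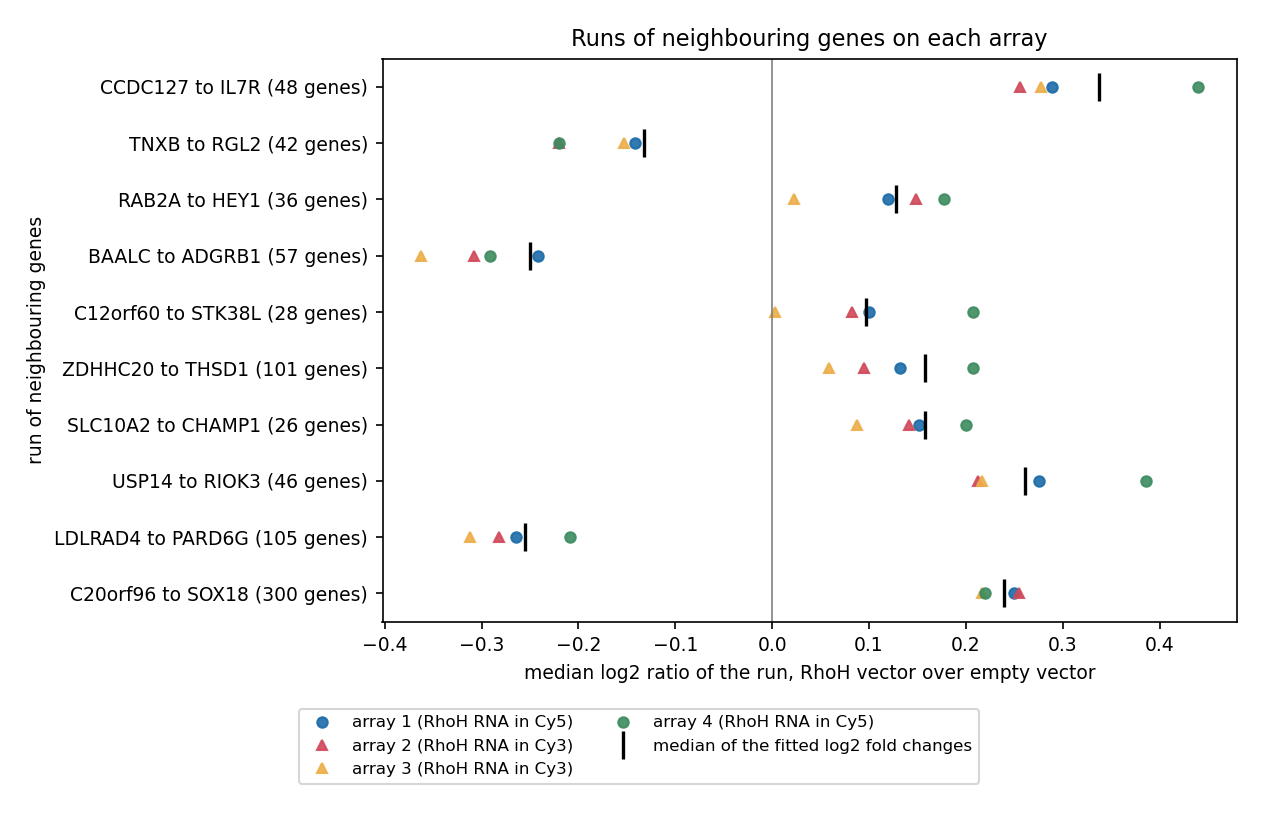
Median log2 ratio of the RhoH vector over the empty vector (horizontal axis) in 10 runs of neighbouring genes (vertical axis, named by the first and last gene). Each point is 1 array, circles have the RhoH RNA in Cy5 and triangles in Cy3, and the bar is the median of the fitted log2 fold changes, which is 0.24 for the run of 300 genes and -0.26 for the run of 105 genes.

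Some named calls rested on the processing. With median centring ITGA6, COL9A2, COL9A3, CBL, DUSP5, KLF6, CCNB1, CDC20, TYMS, RB1, ATF4, HK2, COX8A, ACP5 and JUND did not pass. With the Agilent processed signals COL9A2, SEC11C, PHLDA1, IL3RA, HSPH1, ATF4, PGK1, RPL4, COX8A, FCN1, AIF1 and JUND did not pass. With arrays averaged as technical pairs 1 with 2 and 3 with 4, COL9A3, RPL4, UBASH3A and JUND did not pass. None of these genes changed sign, though averaging arrays as pairs leaves the estimate as it is, so there the sign could not change.

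The dye swap also allowed the dyes to be compared. A dye effect passed the threshold for 33 genes (limma), and 3990 genes had an unadjusted p under 0.05 for it. This count rested on the processing and on single arrays: it was 0 with the Agilent processed signals, with a normexp offset of 0 or without array 2, 277 without array 4, 941 without array 1, 692 without the filter on dim probes and 12895 with median centring.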

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

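The tests of the array sets, those over genes well above background included, were chosen after the values of CD38 and IL15 on each array had been seen. The gap of 1 array from the other 3 was looked for in 113 named genes and 11 array measures. It met the limit for 2 genes and 5 measures, where chance gives about 1 in 20 groups.

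LGALS2 rose by 1.02 on array 1 and by 1.33 to 1.35 on the other arrays. PREX1 rose by 0.79 on array 2 and by 0.57 to 0.59 on the other arrays.

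Array 1 stood apart in brightness. Its share of spots well above background was 74.1% in Cy3 and 84.6% in Cy5, against 49.0% to 50.8% and 54.0% to 54.6% on the others. Its median net signal was 96 in Cy3 and 144 in Cy5, against 54.5 to 56.2 and 49.9 to 60.8. Of the E1A control spots, which the comparisons do not use, 99.7% in Cy5 and 91.2% in Cy3 lay above the 95th percentile of the negative controls on array 1, against 8.18% to 23.3% and 5.15% to 25.5% on the others.

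CD38, ACTG1, RAMP1 and SMAD1 changed more on arrays 3 and 4, and IL15 changed more on arrays 1 and 2. The brightness of array 1 as the whole cause is argued against by arrays 2 and 3, which have the same dye orientation and differed in the same direction as arrays 1 and 4 for each of these 5 genes (median 0.99, 0.73 to 1.34). These 5 genes were picked because the array sets differed, so this holds for them alone. A uniform compression on arrays 1 and 2 as the whole cause is argued against by their slope on arrays 3 and 4, 0.86 over all changed genes (0.84 to 0.89). It is also argued against by 62 of 137 genes well above background throughout that differed and changed more on arrays 1 and 2, such as CSF1R. The reverse slope, of arrays 3 and 4 on arrays 1 and 2, was 0.98. Noise in the set on the horizontal axis lowers such slopes, so 0.86 is not a clean measure of compression. Over the 40 changed genes well above background throughout and changed at least 2-fold the slope was 0.74 (0.68 to 0.81). Of these, 37 were larger on arrays 3 and 4, so a partial compression of large ratios stays open. Across genes the difference of arrays 1 and 4 correlated with that of arrays 2 and 3 (r = 0.38, 95% bootstrap interval 0.36 to 0.40), but a deviation shared by arrays 3 and 4 alone, which have 1 scan day, gives this too, so whether arrays 1 and 2 hold one RNA preparation stays open. Culture and scan day cannot be told apart for these genes, because 0 scan days hold arrays of both sets. Arrays 1 and 2 were scanned on different days and read similar values for CD38 (-1.56 and -1.54) and IL15 (-2.62 and -2.44). A deviation of the day of arrays 3 and 4 alone would leave these values alike too.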

How the results depend on the processing

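The random block of arrays 1 with 2 and 3 with 4, scan day as the unit and the fit without run genes were chosen after the results were seen. Of 2678 values of the 113 named genes under 24 alternatives to the fit, 2574 kept direction and side of the threshold, 101 kept direction but no longer passed, 1 newly passed and 2 changed sign. Of the 3636 changed genes, between 99.9% and 100% of those measured kept their sign under each alternative. Dropping the dye term or the run genes, another variance prior or threshold, averaged arrays, the random block and scan day leave the estimate as it is. Under these the sign could not change. Scan day as the unit gives the same RhoH term and p-values as averaged pairs 1 with 2 and 3 with 4 by construction, so it adds no separate check.

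Where a result below left the range of 1.5 times its value, turned or changed side, the cause was not tested. The counts of higher and lower genes (1761 and 1875) were 888 and 1020 with the Agilent processed signals, 885 and 1020 with the series table, 224 and 1166 with median centring, 1041 and 1137 without the dye term, 1103 and 1221 with averaged pairs 1 with 2 and 3 with 4 or with scan day as the unit, 2727 and 2817 with averaged pairs 1 with 3 and 2 with 4, and 800 and 921 at an adjusted p under 0.01, a stricter threshold by construction. Leaving out 1 array gave 934 to 1738 higher and 1088 to 1815 lower, the lowest without array 2 (934 and 1088) and next without array 3 (1118 and 1155). At least 2-fold counts (13 and 38) were 62 and 126 with the processed signals and with the series table, 32 and 93 with a normexp offset of 0, and 12 to 15 and 32 to 43 with 1 array left out.

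The dye effect (33 genes) gave 0 genes with the processed signals, the series table, a normexp offset of 0, the trend and robust prior, scan day as the unit and an adjusted p of 0.01. It gave 9 with the mean of a gene's probes, 58 with array weights, 60 without run genes, 66 with the strict filter, 70 without background subtraction, 72 with every probe tested, 692 without the filter, 12895 with median centring, which leaves the dye trend in place, and 0 to 941 with 1 array left out (941 without array 1, 0 without array 2, 277 without array 4). Lists called higher (0) were 1 without the filter, 1 with fry and 0 to 1 with 1 array left out. Lists called lower (4) were 8 with median centring, 7 without the filter, 0 with an estimated correlation and 3 to 9 with 1 array left out (9 without array 1, 7 without array 2).

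RHOH was at 0.11 in the fit, at -0.014 with median centring, at 0.11 and past the threshold (adjusted p = 0.048) with averaged pairs 1 with 3 and 2 with 4, and at 0.09 to 0.14 with 1 array left out. ITGAE turned from 0.053 to -0.076 with median centring, and neither value passed. With median centring all tested genes had a median of -0.089, and both RHOH and ITGAE stayed above it. With pairs averaged or a random block, a call rests on the assumed pairing, and the random block, fitted without a dye term, had a correlation of -0.40. Probes below the filter limit what could be tested, as for CCND1, IL2RA and ANXA1.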

Other observations

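The tests on the genes between and around the HLA class II genes, on genes 10 places apart and on the divisions of the arrays, the search for runs and the fit without run genes were chosen after results had been seen. In addition to those named in the report, runs of neighbouring genes rose from RAB2A to HEY1 (36 genes, median 0.13, 12 rose and 3 fell), from ZDHHC20 to THSD1 (101 genes, 0.16, 47 and 8), from SLC10A2 to CHAMP1 (26 genes, 0.16, 13 and 0) and from C12orf60 to STK38L (28 genes, 0.10, 11 and 7), and fell from TNXB to RGL2 (42 genes, -0.13, 1 and 19). Since runs hold whole windows, the medians from RAB2A to HEY1, C12orf60 to STK38L and TNXB to RGL2 lay within the limits of -0.15 and 0.14. CCL3, CSF1R, FCN1, AIF1 and UBASH3A also differed between the array sets, and of the 51 genes that changed at least 2-fold, 46 changed more on arrays 3 and 4.

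The RHOH probe was among the brighter ones. Of 1719 tested genes at least as bright, 404 passed the threshold and 41 of these changed by at least 0.5 on the log2 scale, while RHOH was at 0.11. Whether its probe reads the vector's transcript was not tested.

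The number of changed genes was compared with other divisions of the 4 arrays into 2 and 2. Of 3 divisions, 1 gave as many as 3636 genes, the one by the labels, and the highest of the others was 0. The fits of the other divisions leave the RhoH effect in the residual spread, and with a RhoH term arrays 1 and 2 differed from arrays 3 and 4 at 156 genes. So few divisions cannot give a share under 0.05.

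A candidate explanation of the shared change of neighbouring genes is that the RhoH-vector and empty-vector cells differ in copy number over these stretches. The correlation with the 2 neighbours (0.30, and 0.17 outside the runs) fits that hypothesis, as does a run over 300 of 304 tested genes of 1 chromosome. Array noise is argued against, because runs found on arrays 1 and 2 alone kept a median of 0.18 on arrays 3 and 4, on the same side in 11 of 11. Adjacent spots (r = 0.021) do not account for it either. Similar probes of gene families as the whole cause are argued against by the correlation of genes 10 places apart (r = 0.14). That value includes the run genes, so such probes stay open for the 0.17 outside the runs, which does not tell them from copy number. A response to RhoH that acts on whole stretches stays open, no DNA was measured, and TERT, BMP7, SYBU and SQLE lie in such runs while CD38, IL15, BANK1 and ACTG1 do not.

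The fall of 15 of 24 antigen presentation genes was set against changes of their region. Genes off the list were taken here and below without other HLA genes, MICA and MICB. The 71 such genes tested between the HLA genes had a median of -0.00285 (-0.044 to 0.030), which argues against an even loss of the whole region. A loss of the class II part alone stays open, because 1 tested gene off the list lies between the class II genes (BRD2, -0.026). Together with the nearest tested off-list genes on both sides, 21 genes had a median of -0.038 (95% bootstrap interval -0.089 to 0.0090). Of these 1 was lower and 1 higher, while the 8 class II members had a median of -0.33. A loss confined to the class II genes would leave those neighbours unmoved. The run from TNXB to RGL2 fell (-0.13), but it holds class II members of the list, so its fall is not separate support. The 17 members from the first to the last HLA gene of the list had a median of -0.26 and the 7 outside that stretch -0.094. Of these 7, 3 fell (CTSS, CD74 and B2M, the last 2 chosen after their values were seen). TAPBP (0.060) counts among the 7 because the stretch ends at the outermost HLA genes, so not all 7 need lie far from it. A part played by position stays open. Cross-reading of similar HLA probes is argued against as the whole cause by the 6 of 11 members that are not HLA genes and fell. With the run genes left out the list was still called lower (adjusted p = 0.0063), with 0.34 under an estimated correlation as the highest over the alternatives. An effect of the vector was not tested, and the RHOH probe was at 0.11 (adjusted p = 0.096).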
